A study of Mus musculus with 22 samples.

How the data were processed

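RNA was measured in pancreatic β-cells sorted by flow cytometry from 22 male mice of mixed background, aged 3 months. All mice carried the diphtheria toxin receptor in α-cells (GluDTR), δ-cells (SstDTR) and γ-cells (PpyDTR), so that diphtheria toxin (DT) removes these cells and leaves islets of β-cells. DT-treated and control mice were taken 1 month after ablation, either after 8 h of fasting or after the same fast followed by 2 h of refeeding. The labels do not say whether control mice received an injection without toxin, so each DT against control value compares toxin-treated mice with controls of unstated treatment. The 4 groups were fasted control (n = 5), fasted DT (n = 6), refed control (n = 5) and refed DT (n = 6). Each library came from a different mouse, since every mouse number occurs once. Per the labels, RNA was extracted with a column kit for small samples, cDNA was made and amplified with a SMARTer kit for low input, and tagmented Nextera XT libraries were sequenced as single-end reads on a HiSeq4000.

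The deposited table holds 1 column per mouse with the read count of each of 52327 gene symbols. Per the submitters' processing notes, the tools were STAR 2.7.2b, HTSeq 0.9.1 and DESeq2 1.28.1 with genome build GRCm38.p6. Their parameters, the strand setting and the annotation release are not stated. The values were checked to be whole numbers with different totals per mouse, and the table has 0 columns that belong to no mouse. Gene positions were taken from the RefSeq annotation of the same build, and transcript sequences from the protein-coding transcripts of GENCODE. Reads carried no molecular identifiers, so intervals and detection limits cover counting error only.

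Of the 52327 genes, 24242 had no count in any library and 14064 passed the expression filter of edgeR (filterByExpr by group). A further 14021 genes with counts were not tested, and they held at most 0.176% of the counts of a library. Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, a coefficient for each group, robust quasi-likelihood fits and F tests for 7 comparisons, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05 and no minimum fold. The comparisons were DT against control in fasted mice, DT against control in refed mice, refed against fasted in control mice, refed against fasted in DT mice, the difference between the DT effects (interaction), and the averages of the DT effects and of the feeding effects. The common biological coefficient of variation was 0.373. Standard errors of log2 fold changes were derived from the F statistic. Levels are CPM with TMM-scaled library sizes, given as mean ± SD, and log2 CPM values used a prior count of 2.

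Gcg, Sst and Ppy were compared between DT and control mice within each feeding state by two-sided exact permutation tests of the mean log2(CPM + 1), over all 462 splits of 11 mice, with adjustment over the 6 tests. The smallest p that these splits can give is 0.00216. Libraries with a count of 0 were given the level of 3 counts as their detection limit. Shares of counts in single libraries carry 95% Wilson intervals.

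38 gene lists were fixed before the data were examined, as were the comparisons, the tests, most alternatives and the rule for named genes. The lists cover markers of other pancreatic cell types, β-cell function, responses to nutrients, hormones and stress, and measures of sample quality. Each list with at least 3 tested genes (36 lists) was tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within a comparison. The same test with an estimated correlation, and fry, were run beside it. For each list, members past the threshold were counted over all genes and adjusted over the list alone. The genes named for a comparison are the 10 with the largest change in each direction among called genes with a mean log2 CPM of at least 1 that stayed called in every fit with 1 library left out. Where fewer than 5 met this in a direction, the list was filled up to 5 with called genes by smallest p, and where none was called, the 3 with the smallest p are given as values. Gene models without a name of their own were excluded. Ins1, Ins2, Gcg, Sst and Ppy were always included, as were up to 4 members of each described list with the smallest p. Genes named outside this rule are marked as chosen after their values were seen.

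The relation between 2 effects was described by Pearson's r and Spearman's rho across genes and by the overlap of called genes against the product expected by chance. Genes are not independent replicates, so no p was computed across genes, and the spread of r was taken from a jackknife over libraries. The tests were run on simulated data with the means, spread and library sizes of the table. For each comparison 67, 67 and 66 genes were changed by 1.5-, 2- and 4-fold. Apart from that, libraries differed by size and chance only. The share recovered depends on how many genes change, so it need not hold for the real comparisons. The share of simulated 2-fold changes that edgeR recovered was 43.3% for DT in fasted mice, 46.3% for DT in refed mice, 26.9% for the interaction, 59.7% for DT averaged over feeding, and 40.3% and 44.8% for refeeding in control and DT mice. At 1.5-fold it was 16.4%, 11.9%, 4.48%, 43.3%, 7.46% and 14.9% in the same order.

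Alternatives set at the same time were RLE scaling, no scaling beyond library size, no expression filter, a stricter filter (5 CPM in at least 5 libraries), DESeq2 1.42.0, limma voom with and without sample weights, fits without the robust option, the hormone genes removed before scaling, covariates for acinar markers or for endothelial, mesenchymal and immune markers, 1 surrogate variable from sva 3.50.0, the groups compared alone, other pseudocounts for the hormones, and leaving out each library in turn. After seeing the data, a covariate for a library class defined by the GC content of transcript 5′ ends, the slope itself as a covariate, the libraries of the larger class alone, and the fit without refed DT mice 13 and 20 were added. For the gene lists, no scaling, removal of the hormone genes, the acinar covariate and the fit without these 2 mice were also added after seeing the data. Each count of genes was compared with 100 splits of the same libraries. No date, cage or sequencing run is given in the labels. Mice 1 to 11 were fasted and mice 12 to 22 refed, so that any order of processing that follows the numbers cannot be told apart from feeding. Among fasted mice 1 to 5 were controls and 6 to 11 DT mice, so such an order cannot be told apart from DT in fasted mice either. It also enters the interaction and the DT average. Refed DT mice carry the numbers 13 to 17 and 20 and refed controls 12, 18, 19, 21 and 22. The numbers of both treatments thus interleave only in part there, and such an order is not fully separated from DT.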

Results

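The study asks how β-cells work in islets from which the other endocrine cells have been removed, and the libraries compare β-cells of control and DT mice, fasted or refed. How complete the ablation was in the islets was not measured in these libraries of sorted β-cells. Expression was measured in sorted β-cells of 22 mice, with 1 library per mouse: 5 fasted control, 6 fasted DT, 5 refed control and 6 refed DT mice. Total counts ran from 17466967 to 22260048 in fasted control mice, from 16584117 to 23488749 in fasted DT mice, from 16803188 to 22354107 in refed control mice and from 18995892 to 24988880 in refed DT mice. The insulin genes Ins1 and Ins2 took 49.2% ± 1.59 (SD, n = 5) of the counts in fasted control mice, 47.7% ± 2.07 (n = 6) in fasted DT mice, 45.6% ± 3.46 (n = 5) in refed control mice and 49.6% ± 10.2 (n = 6) in refed DT mice. Correlations of log2 CPM between pairs of libraries lay between 0.877 and 0.982, and 0 libraries were identical. Positions are given on GRCm38.p6. Values of Ins1, Ins2, Hspa8, Hspd1, Hspe1 and ribosomal protein genes are uncertain, because reads can be shared with close copies.

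Gcg and Sst transcripts were lower in sorted β-cell libraries of DT than of control mice in both feeding states. Whether they came from β-cells or from α- and δ-cells among the sorted cells was not tested. Their fall is therefore not shown to be a change within β-cells. Gcg, which encodes glucagon (chromosome 2, 62474530 to 62483653), had a median of 77.4 CPM (range 1.3 to 241, n = 5) in fasted control mice and 0.146 CPM (0.0529 to 0.833, n = 6) in fasted DT mice. After refeeding the medians were 158 CPM (56.0 to 172, n = 5) and 0.461 CPM (0 to 26.0, n = 6). Sst, which encodes somatostatin (chromosome 16, 23889573 to 23891342), had medians of 30.3 and 0.0475 CPM in fasted control and DT mice and of 56.0 and 0.0496 CPM in refed control and DT mice. Ppy, which encodes pancreatic polypeptide (chromosome 11, 102099931 to 102101319), had medians of 10.6 and 3.45 CPM in fasted mice and of 31.0 and 13.5 CPM in refed mice. Sst had a count of 0 in 2 fasted DT and 3 refed DT libraries, which allows up to 0.274 CPM, and Gcg had a count of 0 in 1 refed DT library, which allows up to 0.147 CPM.

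The difference in mean log2(CPM + 1) between DT and control mice was −4.79 for Gcg in fasted mice (exact permutation p = 0.00216, adjusted p = 0.00649) and −5.80 in refed mice (exact permutation p = 0.00433, adjusted p = 0.00649). For Sst it was −4.45 in fasted mice (exact permutation p = 0.00433, adjusted p = 0.00649) and −5.54 in refed mice (exact permutation p = 0.00216, adjusted p = 0.00649). Ppy differed by −1.72 in fasted mice (exact permutation p = 0.0216, adjusted p = 0.0260). Its difference of −0.89 in refed mice did not pass the test (exact permutation p = 0.288). Refed DT mouse 13 held the highest Gcg level among DT mice, 26.0 CPM, within the range of fasted control mice and below that of refed control mice, with Sst at 0 CPM and Ppy at 15.9 CPM, and fasted DT mouse 8 the highest Sst level, 4.71 CPM. The Ppy difference in fasted mice lost its call without any 1 of fasted control mice 1 and 2 and fasted DT mice 6, 10 and 11, with differences from −1.69 to −1.30.

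**Figure D1:**
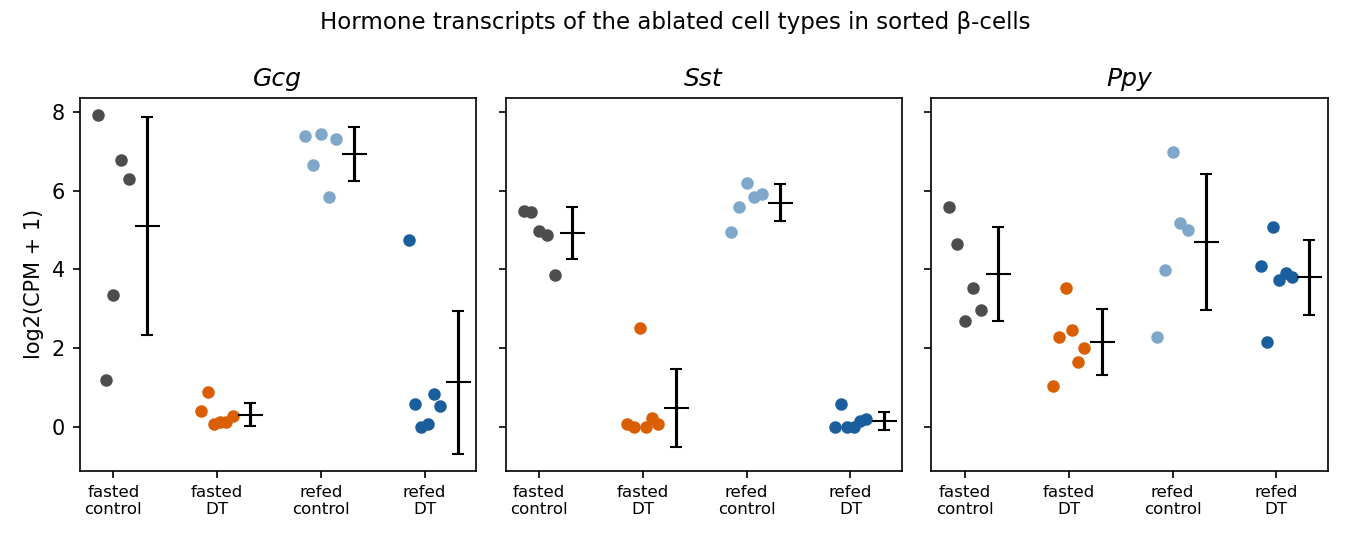
Level of Gcg, Sst and Ppy in every library, as log2(CPM + 1), by group; each point is a mouse and bars give the mean with its SD. Sst and Gcg lie lower in DT than in control mice in both feeding states, with Gcg of refed DT mouse 13 at 4.75 on this scale.

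The comparison of DT with control mice in the fasted state asks what ablation aimed at α-, δ- and γ-cells changes in β-cells at rest. Apart from Sst, which fell by 5.29 on the log2 scale (SE 0.91), 3 genes changed, all higher in DT mice. Without fasted DT mouse 8 the Sst value was −9.02. Luc7l, which encodes a component of U1 splicing complexes, rose from 51.3 ± 8.71 to 88.9 ± 18 CPM (log2 fold change 0.79 ± 0.13 SE; chromosome 17, 26252899 to 26285510). Rbm5, a regulator of splicing, rose from 55.9 ± 5.92 to 85.3 ± 11.5 CPM (0.61 ± 0.10; chromosome 9, 107740495 to 107771007). Atg16l2, a relative of an autophagy gene, rose from 31.5 ± 3.63 to 46.3 ± 5.74 CPM (0.56 ± 0.10; chromosome 7, 101286325 to 101302267). Each of these 4 genes had an adjusted p of 0.0390 with edgeR, and Gcg, with a log2 fold change of −8.45 ± 1.58, had 0.0630. Ins1 and Ins2 differed by 0.01 ± 0.24 and −0.12 ± 0.21 and were not called.

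Of 14064 genes, 3 were higher and 1 lower in fasted DT mice, with 1172 at an unadjusted p under 0.05. DESeq2 called 54 genes and limma voom 4. None of the 4 calls survived every fit with 1 library left out: the count was 0 without any 1 of fasted control mice 1, 2, 4 and 5 or fasted DT mice 6, 9 and 10, 1 without mouse 8, and 11 without mouse 3. Among fasted mice the controls carry the numbers 1 to 5 and the DT mice 6 to 11.

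Gene groups moved little in fasted DT mice, and the called groups were lower. ATF4 and amino acid response genes had a median log2 fold change of −0.26, with 2 of 19 members above 0; none passed the test alone, and the members with the smallest p were Cebpb (2.96 ± 1.18), Nupr1 (−1.08 ± 0.48) and Phgdh (−0.64 ± 0.32). The list's adjusted p was 0.0201 (adjusted p = 0.526 with an estimated correlation). Glucocorticoid-induced genes had a median of −0.31 over 10 members, among them Sgk1 (−0.75 ± 0.41) and Mt1 (−0.70 ± 0.51), with an adjusted p of 0.0284 (adjusted p = 0.311 with an estimated correlation). FoxO and fasting response genes had a median of −0.18 over 20 members, among them Ppargc1a (−0.76 ± 0.30), with an adjusted p of 0.0369 (adjusted p = 0.311 with an estimated correlation). The 27 cAMP pathway genes had a median of −0.11, with the CREB-regulated kinase Sik1 at −1.41 ± 0.58 and Sik2 at −0.67 ± 0.20, and an adjusted p of 0.0369 (adjusted p = 0.526 with an estimated correlation). In each of these 4 lists 0 members passed over all genes and 0 adjusted over the list alone. Without refed DT mice 13 and 20 the FoxO and cAMP lists lost their calls, each with an adjusted p of 0.0606, at medians of −0.20 and −0.13. With acinar markers as a covariate the FoxO list lost its call at a median of −0.18 (adjusted p = 0.0750).

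The same comparison in refed mice asks what this ablation changes while β-cells respond to food. Besides Sst, which fell by 8.62 on the log2 scale (SE 1.12, adjusted p = 0.00288), 3 genes were higher and 1 lower in DT mice. Selenbp1, a methanethiol oxidase, rose from 1.11 ± 0.38 to 4.88 ± 1.93 CPM (2.12 ± 0.34, adjusted p = 0.0227; chromosome 3, 94933083 to 94944758). Dlk1, an imprinted gene for a Notch ligand relative, rose from 1.33 ± 0.415 to 6.02 ± 3.30 CPM (2.17 ± 0.40, adjusted p = 0.0496; chromosome 12, 109452485 to 109463336). Slc35f1, a solute carrier gene, fell by 1.90 (SE 0.33, adjusted p = 0.0380), from 2.61 ± 0.779 to 0.696 ± 0.241 CPM. Duxbl1, a homeobox gene near the detection limit and chosen after its values were seen, rose by 4.72 ± 0.83 (adjusted p = 0.0380). Gcg, at −4.96 ± 1.26, was not called (adjusted p = 0.178). Without refed DT mouse 13 it was −8.54 and called (adjusted p = 0.00725 with edgeR). Not called either were Ins1 (0.52 ± 0.24) and Ins2 (0.30 ± 0.21).

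In total 3 genes were higher and 2 lower, with 1410 at an unadjusted p under 0.05; DESeq2 called 94 genes and limma voom 1. Sst alone stayed called in every fit with 1 library left out. The count was 52 without refed DT mouse 20, 13 without mouse 13, 2 without mouse 17 and 1 without any 1 of refed control mice 12, 19, 21 and 22 or refed DT mouse 15. With mice 13 and 20 both left out, an alternative added after seeing the data, it was 175.

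In refed DT mice the 79 ribosomal protein genes had a median of 0.20, with 74 above 0; 0 passed over all genes and 2 adjusted over the list alone, among them Rps19 (0.42 ± 0.10) and Rps24 (0.32 ± 0.09). Their adjusted p was 3.28e-13 (adjusted p = 0.688 with an estimated correlation). Cholesterol synthesis genes had a median of 0.36 over 25 members, led by Srebf2 (0.48 ± 0.14), a master regulator of the pathway, and Fdft1 (0.68 ± 0.21), with 1 member past the threshold adjusted over the list alone and an adjusted p of 8.44e-05 (adjusted p = 0.688 with an estimated correlation). The 11 mitochondrially encoded genes had a median of 0.59, with mt-Nd2 at 0.73 ± 0.32, and an adjusted p of 0.00226 (adjusted p = 0.688 with an estimated correlation). Lists called lower were ER chaperone and unfolded protein response genes (median −0.14, Derl1 −0.25 ± 0.09, adjusted p = 0.0183), glycolysis genes (median −0.14, Pkm −0.25 ± 0.09, adjusted p = 0.0233) and hypoxia response genes (median −0.32, Ankrd37 −0.63 ± 0.23, adjusted p = 0.0179). These 4 lists had 0 members past the threshold over all genes and 0 adjusted over the list alone, and for each of them the adjusted p was 0.688 with an estimated correlation. Without refed DT mice 13 and 20 the mitochondrially encoded (median −0.15, adjusted p = 0.316), glycolysis (−0.16, adjusted p = 0.0707) and hypoxia lists (−0.16, adjusted p = 0.290) lost their calls. Called in that fit, and not with all libraries, were fatty acid synthesis genes (median 0.28, adjusted p = 0.000755; adjusted p = 0.248 with an estimated correlation) and circadian clock genes (−0.43, adjusted p = 0.00210; adjusted p = 0.433 with an estimated correlation). So were interferon-stimulated genes (−0.40, adjusted p = 0.0113; adjusted p = 0.629 with an estimated correlation) and proliferation genes (−0.27, adjusted p = 0.0190; adjusted p = 0.773 with an estimated correlation). Immune-cell markers were called lower there (−1.08, against 1.21 with all libraries; adjusted p = 0.0303; adjusted p = 0.895 with an estimated correlation).

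Whether the DT effect differed between feeding states was tested by the interaction. 1 gene passed: Selenbp1, whose DT effect was 3.18 ± 0.46 larger on the log2 scale in refed than in fasted mice (adjusted p = 0.0109). Its mean level was 4.74 ± 2.01 CPM in fasted control, 2.28 ± 0.86 in fasted DT, 1.11 ± 0.38 in refed control and 4.88 ± 1.93 in refed DT mice. No gene was called in the other direction; the 3 with the smallest p were Cadps, a priming factor of granule exocytosis (−1.95 ± 0.47), Gas2 (−1.32 ± 0.32) and Atp9a (−0.68 ± 0.14), each with an adjusted p of 0.445. Cadps passed when adjusted over the 30 secretory granule and exocytosis genes alone (adjusted p = 0.0123), and the p53 target Cdkn1a (1.82 ± 0.41) when adjusted over the 9 p53 and senescence genes alone (adjusted p = 0.00216). Such an adjustment does not cover the number of lists and comparisons searched, and neither gene was called over all genes. With edgeR 1004 genes had an unadjusted p under 0.05, DESeq2 called 20 and limma voom 0.

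Called by the interaction were ribosomal protein genes (median 0.15, adjusted p = 4.36e-06), ATF4 and amino acid response genes (median 0.42, adjusted p = 0.00227), glucocorticoid-induced genes (median 0.65, adjusted p = 0.00243), cholesterol synthesis genes (median 0.35, adjusted p = 0.00490) and fatty acid synthesis genes (median 0.18, adjusted p = 0.0413), all higher, and ER chaperone and unfolded protein response genes, lower (median −0.23, adjusted p = 0.0232). None of the 6 calls held with an estimated correlation, where the adjusted p was 0.634 for ribosomal protein and ER chaperone genes, 0.424 for ATF4, 0.242 for glucocorticoid-induced, 0.661 for cholesterol synthesis and 0.512 for fatty acid synthesis genes. Members with the smallest p included Rpl27a (0.53 ± 0.19), Slc3a2 (0.45 ± 0.16), Errfi1 (1.16 ± 0.41), Fdft1 (0.74 ± 0.30), Fads2 (0.86 ± 0.43) and Dnajb9 (−0.56 ± 0.25). No member passed over all genes or adjusted over its list alone. Without refed DT mice 13 and 20 the ATF4 list lost its call (median 0.21, adjusted p = 0.0928). In that fit immune-cell markers were also called (−2.21, against 0.37 with all libraries; adjusted p = 0.00127; adjusted p = 0.613 with an estimated correlation). So were proliferation genes (−0.68, adjusted p = 0.00141) and interferon-stimulated genes (−0.43, adjusted p = 0.0104), each with adjusted p = 0.588 with an estimated correlation.

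Averaged over feeding, 15 genes were higher and 14 lower in DT mice, with 1678 at an unadjusted p under 0.05. Sst fell by 6.96 (SE 0.72, adjusted p = 7.65e-05), as did Gcg (−6.70 ± 1.01, adjusted p = 0.0128) and Gucy2c, the guanylate cyclase receptor of guanylins (−0.83 ± 0.14, adjusted p = 0.0209), the latter from 48.8 ± 9.99 to 27.3 ± 4.44 CPM in fasted and from 98.8 ± 26.0 to 55.6 ± 16.1 CPM in refed mice. Srsf7, an SR splicing factor (chromosome 17, 80200080 to 80207369), rose by 0.54 ± 0.09 (adjusted p = 0.0128), from 105 ± 18.1 to 161 ± 28.3 and from 126 ± 13.2 to 174 ± 13.7 CPM. These 4 genes stayed called in every fit with 1 library left out. Sst was −8.82 without fasted DT mouse 8, and Gcg was −8.51 without refed DT mouse 13. Dlk1 (1.64 ± 0.28), the helicase gene of splicing and RNA export Ddx39b (0.33 ± 0.06), Atg16l2 (0.38 ± 0.07) and Cenps (0.96 ± 0.18) were also higher, and Slc35f1 (−1.30 ± 0.22) and Enpp5 (−0.50 ± 0.09) lower, with adjusted p from 0.0209 to 0.0333. Fosb, an immediate-early gene, rose by 1.00 ± 0.20, and Rgs16, a regulator of G protein signalling, fell by 0.75 (SE 0.15).

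Among lists in this average, ribosomal protein (median 0.12, adjusted p = 2.34e-07), cholesterol synthesis (median 0.19, adjusted p = 0.0180) and mitochondrially encoded genes (median 0.37, adjusted p = 0.0192) were called higher and hypoxia response genes lower (median −0.26, adjusted p = 0.00713), each with adjusted p = 0.816 with an estimated correlation. Without refed DT mice 13 and 20, in which mitochondrially encoded genes took 1.36% and 1.59% of counts, that list lost its call (median −0.018, adjusted p = 0.996). Circadian clock genes were called lower in that fit (median −0.25, adjusted p = 0.0103; adjusted p = 0.661 with an estimated correlation). With acinar markers as a covariate the mitochondrially encoded list had a median of 0.35 and an adjusted p of 0.0508. Of the members of the 4 lists 0 passed over all genes, while 1 ribosomal protein gene and 2 hypoxia response genes, P4ha2 (−0.34 ± 0.11) and Ndrg1 (−0.29 ± 0.11), passed adjusted over the list alone. β-cell identity genes were not called in this average (29 members, median 0.09, 0 past the threshold, adjusted p = 0.428), nor were secretory granule and exocytosis genes (median −0.03, adjusted p = 0.346), ion channel and calcium handling genes (median 0.06, adjusted p = 0.540) or islet hormone and neurotransmitter receptors (median −0.06, adjusted p = 0.786). The count of genes without 1 library ranged from 4 without refed control mouse 12 to 69 without refed DT mouse 20, and DESeq2 called 189.

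Across the 14064 genes, the DT effects in fasted and refed mice had a Pearson r of 0.157 (jackknife SE 0.156) and a Spearman rho of 0.133. Sst was lower in both, where chance would give 0.000142 genes lower in both, and 0 genes were higher in both.

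Far more genes were called between refed and fasted mice than between DT and control mice. An order of processing by mouse number cannot be told apart from feeding in these calls. In control mice 1537 genes were higher and 1735 lower 2 h after refeeding, 340 and 737 of them by at least 2-fold. Nr4a2, an immediate-early nuclear receptor gene, rose by 3.05 ± 0.51 and the CREB target Sik1 by 2.96 ± 0.60, from 2.58 ± 2.68 to 19.8 ± 12.1 CPM. The oxytocin receptor gene Oxtr rose by 3.21 ± 0.77, Spry4, an inhibitor of receptor tyrosine kinase signalling, by 3.40 ± 0.77, the phosphodiesterase gene Pde10a by 2.53 ± 0.40, and Meltf and Dapl1 by 2.88 ± 0.61 and 2.71 ± 0.39. The chaperone gene Hspa8 rose from 179.7 ± 34.9 to 1169 ± 447 CPM and Hsph1 by 3.05 ± 0.31, from 31.5 ± 7.78 to 262 ± 114 CPM (adjusted p = 1.99e-06; chromosome 5, 149616843 to 149636498). Fh1, fumarate hydratase of the citric acid cycle, rose by 2.32 ± 0.16, from 63.2 ± 5.83 to 316 ± 19 CPM (adjusted p = 1.87e-08; chromosome 1, 175601378 to 175625635).

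Among the genes that fell in control mice were Trib3, a pseudokinase gene of the ATF4 response (−3.90 ± 0.66, adjusted p = 0.000237), the vesicle protein gene Sv2b (−3.88 ± 0.56) and the receptor tyrosine kinase gene Kit (−3.69 ± 0.76). Rgs12, Klhl24, Radil, Klf11, Dusp26, Fam221a and Lrrc29 had log2 fold changes from −3.49 to −2.72. Klhl24 went from 42.8 ± 13.4 to 5.22 ± 0.779 CPM (adjusted p = 8.64e-08). These 20 genes stayed called in every fit with 1 library left out, as did 2144 of the 3272 calls. Ins1 (−0.16 ± 0.25) and Ins2 (−0.11 ± 0.22) were not called.

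Of 10 heat shock genes, 6 rose and 4 were not called in refed control mice; Hsp90aa1 rose by 2.02 ± 0.19 and Hspd1 by 1.35 ± 0.12. The list's adjusted p was 8.45e-11 (adjusted p = 0.115 with an estimated correlation). Of 30 ER chaperone and unfolded protein response genes 15 rose and 15 were not called, among the former Creld2 (1.67 ± 0.23), Dnajb11 (1.17 ± 0.19) and Pdia6 (0.99 ± 0.15), with an adjusted p of 1.52e-07 (adjusted p = 0.261 with an estimated correlation). Acinar markers were called higher in the same comparison. With them as a covariate 14 of these 15 genes stayed called (median 0.57 against 0.61, adjusted p = 5.14e-08; adjusted p = 0.266 with an estimated correlation). Of 74 oxidative phosphorylation genes 28 rose and 46 were not called, including rises of Ndufc2 (1.11 ± 0.12), Cycs (1.76 ± 0.19) and Atp5g1 (1.35 ± 0.20), with an adjusted p of 2.48e-08 (adjusted p = 0.528 with an estimated correlation). Of 15 CREB target genes 6 rose, with Crem at 1.95 ± 0.23, 2 fell and 7 were not called (adjusted p = 0.00321; adjusted p = 0.261 with an estimated correlation). Of 15 glycolysis genes 8 rose, among them Pgk1 (1.11 ± 0.19) and Aldoa (0.53 ± 0.09), 3 fell and 4 were not called (adjusted p = 0.0421; adjusted p = 0.493 with an estimated correlation). Of 79 ribosomal protein genes 13 rose, with Rpl12 at 0.63 ± 0.11, and 3 fell (adjusted p = 0.0155; adjusted p = 0.871 with an estimated correlation). With acinar markers as a covariate this list lost its call (median 0.11 against 0.15, adjusted p = 0.0795). Adjusted over the list alone, 6 heat shock, 17 ER chaperone, 31 oxidative phosphorylation, 9 CREB target, 8 glycolysis and 12 ribosomal protein genes rose.

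Lists called lower in refed control mice were ATF4 and amino acid response, FoxO and fasting response, p53 and senescence, ion channel and calcium handling, and proliferation genes. Of 19 ATF4 and amino acid response genes 10 fell and 9 were not called; Sesn2, a stress-induced inhibitor of mTORC1 (−1.39 ± 0.16), and the folate enzyme gene Mthfd2 (−1.27 ± 0.27) were among them (adjusted p = 0.00117; adjusted p = 0.493 with an estimated correlation). Of 20 FoxO and fasting response genes 7 fell, including the lipase inhibitor gene Angptl4 (−6.31 ± 0.72), Fbxo32 (−2.24 ± 0.32) and Cpt1a, of mitochondrial fatty acid import (−1.49 ± 0.17), while 2 rose, among them Gadd45a (2.05 ± 0.21), and 11 were not called (adjusted p = 0.0174; adjusted p = 0.261 with an estimated correlation). Of 9 p53 and senescence genes 4 fell, among them Trp53inp1 (−2.31 ± 0.26) and Cdkn1a (−1.77 ± 0.31) (adjusted p = 0.0174; adjusted p = 0.150 with an estimated correlation). Of 24 ion channel and calcium handling genes 6 fell, including Kcnh6 (−0.64 ± 0.15), Trpm4 (−0.70 ± 0.17) and Itpr1 (−0.72 ± 0.20) (adjusted p = 0.0309; adjusted p = 0.493 with an estimated correlation). Of 28 proliferation genes 3 fell, with Ccnb2 at −1.88 ± 0.49 and Nusap1 at −1.67 ± 0.49 (adjusted p = 0.0421; adjusted p = 0.699 with an estimated correlation). With acinar markers as a covariate this list lost its call (median −0.76 against −0.85, adjusted p = 0.0703). Adjusted over the list alone, 10 ATF4, 7 FoxO, 5 p53, 6 ion channel and 2 proliferation genes fell.

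Lists not called in refed control mice still held single changes. Slc30a8, the zinc transporter of insulin granules (−0.95 ± 0.11), and the transcription factor gene Rfx6 (−1.42 ± 0.19) fell among 29 β-cell identity genes, of which 2 rose and 6 fell (adjusted p = 0.560). Immediate-early genes included 2 that rose and 5 that fell of 23 (adjusted p = 0.666), with Fosl2 at 1.72 ± 0.36 and Egr1 at −1.25 ± 0.37. Of 19 circadian clock genes 4 rose and 3 fell, with Per2 at 1.89 ± 0.30 and Rora at −1.12 ± 0.14 (adjusted p = 0.666).

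**Figure D2:**
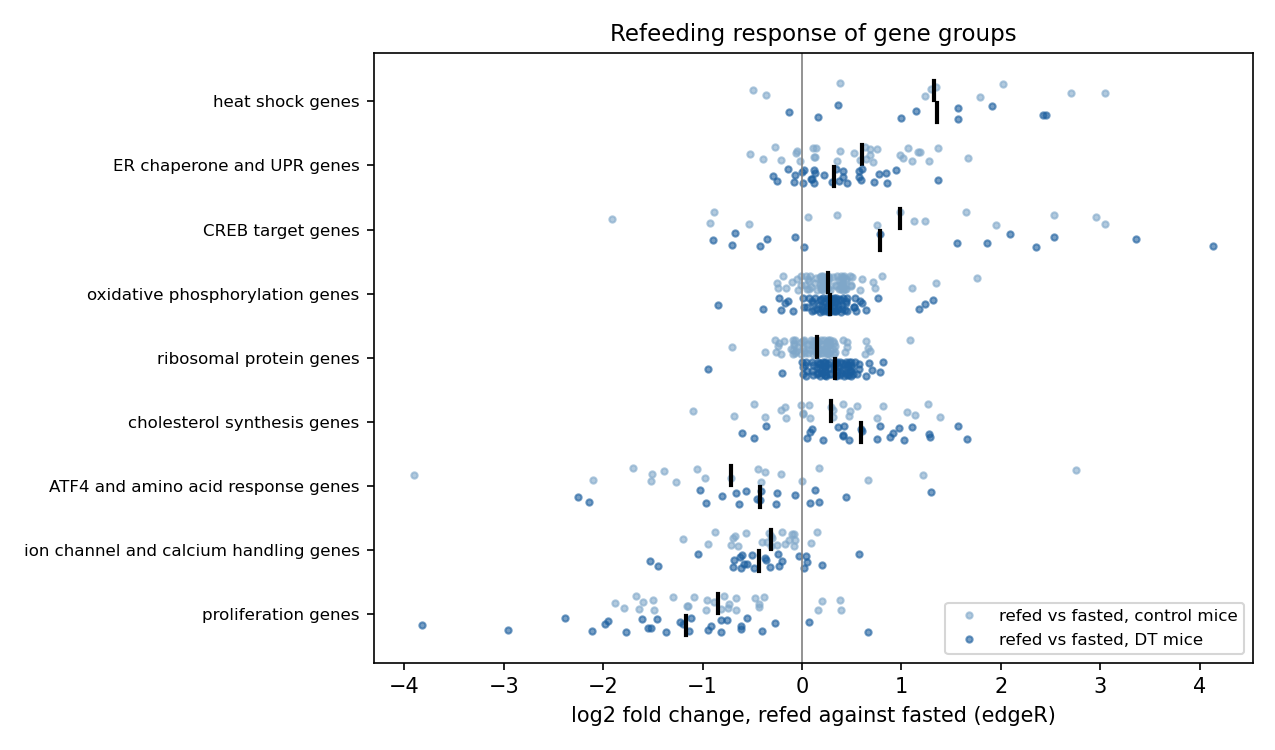
Log2 fold change after refeeding of each member of selected gene lists in control and in DT mice; points are genes and bars mark the list medians. Heat shock genes have medians of 1.32 and 1.36, and ATF4 and amino acid response genes of −0.71 and −0.43, in control and DT mice.

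In DT mice 1521 genes were higher and 1905 lower after refeeding, 278 and 699 of them by at least 2-fold. Sik1 rose by 4.13 ± 0.59, from 0.945 ± 0.49 to 16.8 ± 8.54 CPM, Oxtr by 4.08 ± 0.75, Spry4 by 3.45 ± 0.71, Nr4a1 by 3.36 ± 0.63 and Crem, a cAMP-responsive transcription factor gene, by 2.53 ± 0.21 (adjusted p = 6.40e-08). Fam167a, Dapl1, Fosl2, Cd24a and Tubb6 rose by 3.27 to 2.46. Among the genes that fell were Klf11 (−3.00 ± 0.37), the peroxisomal fatty acid transporter gene Abcd2 (−2.98 ± 0.48) and Klhl24 (−2.88 ± 0.23), as well as Tcp11l2, Rps6ka5, Coq8a, Lrrc29, the glycogen-targeting gene Ppp1r3c, Crebrf and Ccng2, from −2.84 to −2.50. All 20 stayed called in every fit with 1 library left out, as did 2355 of the 3426 calls. Ins1 (0.35 ± 0.23) and Ins2 (0.31 ± 0.20) were not called.

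By group, 7 of 10 heat shock genes rose in refed DT mice, with Hsph1 at 2.45 ± 0.28 and Hspa8 at 2.42 ± 0.25 (adjusted p = 1.52e-10; adjusted p = 0.126 with an estimated correlation). Of 74 oxidative phosphorylation genes 35 rose and 2 fell (adjusted p = 6.24e-10; adjusted p = 0.377 with an estimated correlation). Of 79 ribosomal protein genes 35 rose, with Rpl27 at 0.78 ± 0.13, and 1 fell (adjusted p = 2.72e-10; adjusted p = 0.377 with an estimated correlation). Of 30 ER chaperone and unfolded protein response genes 12 rose, with Creld2 at 1.37 ± 0.21, and 1 fell (adjusted p = 0.000155; adjusted p = 0.377 with an estimated correlation). Acinar markers were called higher here too. With them as a covariate 26, 20 and 12 of the genes that rose stayed called in the oxidative phosphorylation, ribosomal protein and ER chaperone lists. Of 25 cholesterol synthesis genes 12 rose, including Lss (1.03 ± 0.15), of the step to lanosterol, and 1 fell (adjusted p = 2.24e-05; adjusted p = 0.387 with an estimated correlation). Of 15 CREB target genes 8 rose, with Ppargc1a at 1.86 ± 0.29 (adjusted p = 4.65e-05; adjusted p = 0.139 with an estimated correlation), and of 27 cAMP pathway genes, which share Crem, Sik1 and Pde10a with that list, 9 rose and 2 fell (adjusted p = 0.00197; adjusted p = 0.258 with an estimated correlation). Adjusted over the list alone, 7 heat shock, 41 oxidative phosphorylation, 49 ribosomal protein, 13 ER chaperone, 12 cholesterol synthesis, 8 CREB target and 9 cAMP pathway genes rose.

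Proliferation genes were lower in refed DT mice: 8 of 28 fell, including Mki67 (−2.11 ± 0.52), Bub1b (−2.96 ± 0.70) and Mcm7 (−0.92 ± 0.20), and 1 rose (adjusted p = 0.000164; adjusted p = 0.377 with an estimated correlation). Of 24 ion channel and calcium handling genes 7 fell, with Atp2a3 at −0.58 ± 0.12 (adjusted p = 0.0297; adjusted p = 0.377 with an estimated correlation). Of 12 glucose-induced and ChREBP target genes 4 fell, among them Pklr (−1.38 ± 0.26) and the fructokinase gene Khk (−0.77 ± 0.14), and G6pc2 rose (0.74 ± 0.16) (adjusted p = 0.0385; adjusted p = 0.194 with an estimated correlation). Adjusted over the list alone, 10 proliferation, 7 ion channel and 5 ChREBP target genes fell. ATF4 (3 of 19 fell and 1 rose, adjusted p = 0.168), FoxO (6 of 20 fell and 2 rose, adjusted p = 0.202) and p53 genes (3 of 9 fell and 1 rose, adjusted p = 0.137) were not called as lists, nor were fatty acid synthesis genes (4 of 15 rose, Elovl6 0.67 ± 0.14, adjusted p = 0.0526). Slc30a8 (−1.11 ± 0.10) and the glucose transporter gene Slc2a2 (−1.34 ± 0.22) fell, among 7 lower and 4 higher of 29 β-cell identity genes (adjusted p = 0.492), and of 30 secretory granule and exocytosis genes 2 rose, among them Vgf (2.07 ± 0.40), and 4 fell (adjusted p = 0.751).

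With both treatments averaged, 2416 genes were higher and 3054 lower after refeeding, and 4375 of the 5470 calls held in every fit with 1 library left out. Heat shock genes again held the smallest adjusted p (8.55e-12; 7 of 10 rose; adjusted p = 0.0804 with an estimated correlation), and Klhl24 fell by 2.95 (SE 0.17, adjusted p = 6.74e-11), Hspa8 rose by 2.56 ± 0.18 (adjusted p = 1.60e-09) and Hsph1 by 2.75 ± 0.21. Of 74 oxidative phosphorylation genes 48 rose and 1 fell, and of 28 proliferation genes 16 fell and 1 rose. Ppy rose by 1.52 ± 0.53 (adjusted p = 0.0269), a call that was lost without fasted control mouse 3 (1.40), refed DT mouse 15 (1.33) or refed control mouse 19 (1.02, adjusted p = 0.103). MHC class I genes (4 of 11 fell, adjusted p = 0.317), interferon-stimulated genes (7 of 22 fell, adjusted p = 0.282), prolactin and pregnancy response genes (2 of 9 rose and 1 fell, adjusted p = 0.407), dedifferentiation and progenitor genes (1 of 10 rose and 2 fell, adjusted p = 0.868) and genes kept low in β-cells (1 of 18 rose and 1 fell, adjusted p = 0.961) were not called.

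The refeeding responses of control and DT mice were alike in direction across genes, with a Pearson r of 0.613 (jackknife SE 0.0949) and a Spearman rho of 0.658. In both, 985 genes were higher where chance would give 166, 1064 were lower where chance would give 235, and 4 were called in opposite directions. A gene called in only 1 of these comparisons is not shown to differ, since the interaction called Selenbp1 alone. Without scaling beyond library size 23.1% of the calls in DT mice were higher, against 44.4% with TMM.

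**Figure D3:**
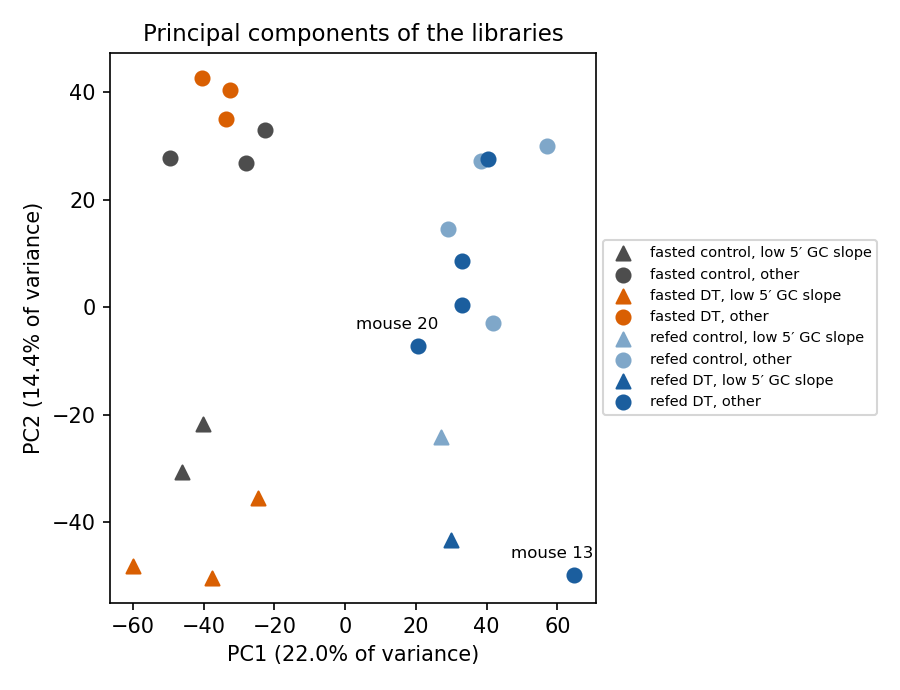
First and second principal components of log2 CPM in the 22 libraries (22% and 14.4% of the variance), coloured by group, with triangles for the 7 libraries low in transcripts rich in GC at the 5′ end. The first component parts fasted from refed mice, and the second parts those 7 libraries and refed DT mouse 13 from most others.

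RNA of other cell types was low but varied between libraries. Acinar markers took 0.819% ± 0.687 of counts in fasted control, 0.744% ± 0.962 in fasted DT, 1.72% ± 1.07 in refed control and 1.78% ± 2.01 in refed DT mice. The acinar list was called higher after refeeding in control (adjusted p = 0.0116; adjusted p = 0.871 with an estimated correlation) and DT mice (adjusted p = 0.00117; adjusted p = 0.709 with an estimated correlation), where Bhlha15, a transcription factor gene of secretory cells, rose and 32 of 33 members were not called. Averaged over feeding, the DT effect had a median of −0.24 for δ-cell markers (Sst fell, 4 tested, adjusted p = 0.159) and 0.15 for α-cell markers (Gcg fell, 8 tested, adjusted p = 0.558), where camera's direction was down. In refed mice acinar markers had a median DT effect of 0.30 while camera's direction was down (adjusted p = 0.686). Ductal (median 0.01, adjusted p = 0.540), endothelial (−0.01, adjusted p = 0.777), mesenchymal (1.84, adjusted p = 0.540), immune (1.20, adjusted p = 0.159) and Schwann-cell markers (−0.08, adjusted p = 0.338) were not called. The lists of γ- and ε-cell hormones, with 2 tested genes, and of erythroid genes, with 0, were too short to test.

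The second principal component mostly followed a measure of the GC content of transcript 5′ ends. Refed DT mouse 13, low on this component (−49.8), was not placed among the 7 libraries described here, but resembled them in part. Its log2 CPM of Zxdc (3.12), Lamp1 (6.69), Rac1 (3.34) and Grb2 (4.03) lay between those of the 7 libraries and those of the rest. These genes, chosen after their values were seen, are lower in the 7 libraries. Mouse 13 is counted among the other 15 libraries wherever these were analysed alone. In 7 libraries (mice 4, 5, 6, 7, 8, 16 and 21) genes whose transcripts are rich in GC at the 5′ end had lower counts, and 1327 genes were lower and 14 higher in these 7 than in the other 15 libraries. They comprised 2 of 5 fasted control, 3 of 6 fasted DT, 1 of 5 refed control and 1 of 6 refed DT mice. Of the 3272 and 3426 genes called after refeeding in control and DT mice, 61 and 83 belonged to those genes, where chance would give 312 and 327. Those genes differ between libraries of the same group, which adds spread in the main fit and can cost calls. The low overlap therefore does not show that the refeeding calls are free of this difference. With the 5′ GC slope as a covariate 3698 and 3889 genes were called.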

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

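The splits of the mice, the 5′ GC tests, the tests on mouse numbers, the fit without refed DT mice 13 and 20 and the use of covariates and of hormone gene removal to weigh patterns were tests chosen after the results were seen, while the interaction with its list tests and these covariates and removal as alternatives were set before the data were examined, and the removal of any 2 refed DT mice before its result was seen.

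Between feeding states, the DT effect on Selenbp1 differed by 3.18 on the log2 scale, and list tests of the same difference gave adjusted p of 4.36e-06 for ribosomal protein genes, 0.00227 for ATF4 and amino acid response genes, 0.00243 for glucocorticoid-induced genes, 0.00490 for cholesterol synthesis genes, 0.0232 for ER chaperone and unfolded protein response genes and 0.0413 for fatty acid synthesis genes with camera. With an estimated correlation none of these lists was called (adjusted p from 0.242 to 0.661). Of 100 splits of the 22 mice, 12 called at least as many genes as the real 1, with 265 as the highest other, so chance cannot be excluded for that count.

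Some libraries lay far from the others of their group. Among 232 groups of values tested, 24 (10.3%) held such a library, where chance gives about 1 in 20 for normally distributed values. For single named genes it was 12 of 184 groups, so the excess lay in the library measures. Some of these are shares or levels near 0, and some are related to each other, so that rate need not hold for them. Total counts were the lowest of its group in fasted control mouse 2 (17466967) and the highest of its group in refed DT mouse 16 (24988880), which also had the lowest 5′ GC slope of refed DT mice (−0.162). Refed DT mouse 13 had a TMM factor of 0.566, an Ins1 and Ins2 share of 69.4% (95% interval 69.39424 to 69.43532) and Gcg at 4.75 on the log2(CPM + 1) scale. Acinar markers took 5.68% (5.67 to 5.69) of counts in refed DT mouse 15. Immune markers took 0.0270% in fasted control mouse 1, 0.0544% in fasted DT mouse 7 and 0.0694% (0.0683 to 0.0706) in refed DT mouse 20. Sst stood at 2.51 in fasted DT mouse 8 and 0.58 in refed DT mouse 14 on the log2(CPM + 1) scale.

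Single named genes lay apart in 12 of 184 groups, on the scale of log2 CPM. High values were those of Sst in fasted DT mouse 8 (2.27), Rgs12 in fasted DT mouse 11 (4.10) and Nr4a1 in fasted control mouse 2 (5.65). Low values were those of Oxtr in refed control mouse 21 (2.55), Klhl24 in fasted control mouse 2 (4.35) and refed DT mouse 14 (1.33), Radil in refed DT mouse 17 (−1.76), Klf11 in fasted control mouse 5 (5.18), Fosl2 and Crebrf in fasted DT mouse 6 (−0.64 and 4.32), and Tcp11l2 and Enpp5 in refed DT mouse 13 (0.26 and 6.21).

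In 7 libraries 1327 genes were lower (median log2 difference −1.36), and their transcripts were rich in GC at the 5′ end (median 68.7% against 59.0%). Among 8256 genes that did not enter the slope defining these libraries, the 734 lower ones had a median 5′ GC content 10.8 percentage points above that of all such genes (95% interval 9.67 to 12), while the 3′ end differed by −0.333. All 4 groups held libraries of both kinds (Fisher exact p = 0.675), which argues against DT or feeding as the sole cause of this division. Among the other libraries the lowest slopes (0.00319 to 0.0245) were those of refed DT mice 13, 14, 15 and 20 and refed control mouse 22. A relation of the slope itself to feeding or DT was not tested. A bias against GC-rich 5′ ends during library preparation is a candidate explanation; the labels give no batch to test it against, though 5 of the 7 libraries carry the numbers 4 to 8.

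The rise of heat shock genes after refeeding was weighed against acinar RNA, the 5′ GC library kind and the order of processing. With acinar markers as a covariate 7 of the 7 called heat shock genes stayed called (median 1.67 against 1.68), and 7 stayed called among the 15 libraries of the other kind alone (median 1.73), which argues against both as the whole cause. Those 15 libraries include refed DT mouse 13, which resembled the 7 libraries left out in part. Order of processing cannot be told apart from feeding: 0 fasted mice carry a number above 12, the lowest of the refed mice. Within groups heat shock genes did not follow the mouse number past the threshold (rho −0.0875, permutation p = 0.417). Refeeding itself, handling and the day of processing stay open.

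Without refed DT mice 13 and 20 the DT comparison in refed mice called 175 genes instead of 5. The refed DT mice left in carry the numbers 14 to 17, and the controls 12, 18, 19, 21 and 22. An order of processing by number is thus hardly separated from DT in that fit. Its count was not set against splits of the mice. Removing the hormone genes called 4, and a covariate of endothelial, mesenchymal and immune markers called 7. Leaving out mouse 13 alone called 13 genes and leaving out mouse 20 alone 52. A cause in a single mouse could therefore not give 175 calls. Neither test decides on the insulin share of mouse 13 or on RNA of those cells. Of the 15 pairs of refed DT mice that can be left out, 1, the pair 13 and 20, called as many. The highest other was 71, for mice 16 and 20, and the median of the others 4. Mice 13 and 20 were also the refed DT mice whose single removal raised the count. Their first rank among pairs was thus partly set in advance and is no separate support. Gcg in mouse 13 (26.0 CPM) lay within the range of fasted control mice (1.3 to 241 CPM) and below that of refed control mice (56.0 to 172 CPM), with Sst at 0 CPM; incomplete ablation in that mouse was not tested and stays open, as does why mouse 20 differs.

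Other splits of the mice were drawn for each count of changed genes, 100 for each. Among fasted mice the controls carry the numbers 1 to 5 and the DT mice 6 to 11, so an order of processing by number cannot be told apart from DT there, nor kept out of the interaction and the DT average, which rest on these mice. For DT in fasted mice 2 splits called at least the real 4 genes, with 370 as the highest other, which excludes chance by the share of splits alone, but the count was 0 without any 1 of mice 1, 2, 4, 5, 6, 9 and 10, 1 without mouse 8 and 11 without mouse 3, and 0 without scaling, without a filter or with 2 groups only. For refeeding 1 split, the real one, called as many in control mice (3272, highest other 1), in DT mice (3426, highest other 411) and on average (5470, highest other 399), so chance is excluded for these 3. For the DT average 1 split, the real one, called as many (29, highest other 14), which excludes chance by the share of splits alone, but the count fell below 14 without any 1 of mice 12 (4), 4 or 8 (5), 6 (6), 1 (7), 5 or 19 (9), 16 or 22 (10), 10 (11) and 17 or 21 (13), was 69 without mouse 20, and was 1 in the other library kind alone. For DT in refed mice 6 splits called at least the real 5, with 206 as the highest other, so chance cannot be excluded. The other splits that called at least 5 genes in refed mice (206, 100, 99, 41 and 9) all kept DT mice 14, 15, 16 and 17 on the same side. They thus carry part of the DT grouping, though other splits that kept these mice together called 0 or 1. The numbers of these mice are also consecutive, so such splits may carry an order of processing by number as well, which was not tested. Splits that call 370 or 265 genes may point to a structure of the samples, which was not identified. The split with 370 put all 5 fasted libraries low in GC-rich 5′ ends on the same side, but another split that did so, with fasted mice 1, 2, 3, 10 and 11 on the other side, called 2 genes, and no structure was tested for the 206 or the 265. Within the libraries of the other kind the real comparison in fasted mice called 1 gene.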

How the results depend on the processing

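The alternatives with the 5′ GC library kind, the libraries of the other kind alone and the removal of refed DT mice 13 and 20, and for lists those without scaling, without hormone genes or with the acinar covariate, were tests chosen after seeing the data; the others were set before the data were examined. No paired analysis was possible because each mouse gave 1 library in 1 condition.

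Sst and Gcg kept their direction and their call in the exact test in both feeding states under the alternatives run. Ppy in fasted mice lost its call without fasted control mouse 1 (−1.30) or 2 (−1.53) and without fasted DT mouse 6 (−1.50), 10 (−1.62) or 11 (−1.69), within a range of −2.02 to −1.30. Counts of genes called after refeeding stayed within 1.5 times the reported ones, except in control mice without scaling (2179) and in the other library kind alone (1895), which has fewer samples. Leaving out 1 library gave 2641 to 3052 in control mice, 2884 to 4399 in DT mice and 5070 to 6286 on average. The correlation of the feeding effects was 0.792 among genes with a mean log2 CPM of 4 or more.

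Counts for DT were unstable. In fasted mice (4 genes) the count was 2 with RLE scaling or hormone genes removed, 0 without scaling, without a filter or with 2 groups only, 54 with DESeq2, 10 with voom and sample weights, 1 in the other library kind alone and 26 without refed DT mice 13 and 20. Without 1 library it ranged from 0 (any of mice 1, 2, 4, 5, 6, 9 and 10) to 11 (mouse 3), with 1 without mouse 8. In edgeR's reported analysis 1172 genes had an unadjusted p under 0.05.

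In refed mice (5 genes) the count was 2 without scaling or with 2 groups only, 1 with the stricter filter, limma voom or the other library kind alone, 94 with DESeq2, 79 with voom and sample weights, 3 with the library kind as covariate and 175 without mice 13 and 20. Without 1 library it ranged from 1 (any of mice 12, 15, 19, 21 and 22) to 52 (mouse 20), with 2 without mouse 17 and 13 without mouse 13.

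For the interaction (1 gene; 1004 at an unadjusted p under 0.05 with edgeR) the count was 0 without scaling, with the stricter filter, with limma voom and in the other library kind alone, 20 with DESeq2 and 14 without mice 13 and 20. Without 1 library it ranged from 1 to 2 (mouse 6). For the DT average (29 genes) it was 4 without scaling, 8 without a filter, 189 with DESeq2, 155 with voom and sample weights, 1 in the other library kind alone and 123 without mice 13 and 20. Without 1 library it was 4 (mouse 12), 5 (4 or 8), 6 (6), 7 (1), 9 (5 or 19), 10 (16 or 22), 11 (10), 13 (17 or 21), 15 (9), 19 (2) and up to 69 (20). Apart from settings with fewer samples or another set of tested genes, the cause was not tested.

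Calls of lists rest on the correlation assumed between genes. With an estimated correlation 0 lists were called in each of the 7 comparisons. With fry 0 were called for DT in fasted mice, in refed mice, on average and for the interaction. For refeeding fry called 13 lists in control mice, 19 in DT mice and 21 on average. The stricter filter left 1 list for DT in fasted mice and 6 for refeeding in control mice, and without refed DT mice 13 and 20 the fasted DT comparison called 2. The mitochondrially encoded genes turned from higher to lower in refed DT mice without mice 13 and 20 (adjusted p = 0.316).

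Scaling shifted the median of all genes by −0.13 for refeeding in DT mice and by −0.14 for the interaction when no factor beyond library size was used. The share of calls that were higher then fell from 44.4% to 23.1% for refeeding in DT mice, from 60% to 0% for DT in refed mice and from 51.7% to 0% for the DT average. For DT in fasted mice it was 100% with RLE scaling, against 75%, and for DT in refed mice 71.3% with DESeq2.

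Reversed directions were found in genes that were not called in the comparison. Without mice 13 and 20 these were Ins1 for DT in fasted mice (−0.0067) and for feeding on average (−0.049), Ins2 for DT in refed mice (−0.013), DT on average (−0.075) and feeding on average (−0.0071), Gcg in the interaction (−0.14), mt-Nd2 (−0.054), mt-Nd4 (−0.25), mt-Nd6 (−0.15) and mt-Rnr1 (−0.074) for DT in refed mice, and mt-Nd4 for DT on average (−0.021). With voom and sample weights they were Ins2 for DT in refed mice (−0.022), DT on average (−0.071), feeding in DT mice (−0.00053) and on average (−0.050), Ins1 for feeding in DT mice (−0.030) and on average (−0.094), Gcg in the interaction (−1.82), Sst for feeding on average (0.40), and mt-Nd4 (−0.11) and mt-Nd6 (−0.0078) for DT in refed mice. With voom they were Gcg in the interaction (−1.15) and Sst for feeding on average (0.10). In the other library kind alone Sst reversed for feeding in DT mice (1.24), on average (0.86) and in the interaction (0.77), and Ins1 (−0.14), Phgdh (0.098) and Mt1 (0.14) for DT in fasted mice. Ins1 reversed in that comparison without a filter (−0.0043), and without scaling Ins1 (−0.045) and Ins2 (−0.024) reversed for feeding on average. Cela3a did so for feeding in control mice with the acinar covariate (−0.032). The cause was not tested.

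With 1 library left out, Sst ranged from −3.81 to 1.13 for feeding in DT mice, from −1.54 to 0.93 on average and from −4.55 to 0.40 in the interaction, with the upper ends without fasted DT mouse 8. Gcg in the interaction ranged from −0.054 to 4.22. Ins1 ranged from −0.033 to 0.062 for DT in fasted mice (below 0 without mouse 3, 5, 6 or 7), from −0.0060 to 0.46 for feeding in DT mice and from −0.065 to 0.15 on average. Ins2 ranged from −0.040 to 0.40 for DT in refed mice, from −0.089 to 0.14 for DT on average and from −0.023 to 0.16 for feeding on average. For Gcg, Ins2 and these feeding effects of Ins1 the lower ends were those without refed DT mouse 13. The cause was not tested.

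Depth limits the values of Gcg and Sst in DT mice: a count of 0 allows up to 0.274 CPM for Sst and 0.147 CPM for Gcg.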

Other observations

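The fit without refed DT mice 13 and 20, the splicing factor list with its alternatives and the use of CREB target genes for a hypothesis were tests chosen after the results were seen, while the CREB list test itself was set before the data were examined and the splits of the mice for the splicing factor list before their result was seen.

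Leaving out refed DT mice 13 and 20, a choice made after seeing the data, gave 175 genes called between refed DT and control mice, 114 higher and 61 lower. In that fit an order of processing by mouse number is hardly separated from DT, and the count was not set against splits. Jup, which encodes plakoglobin of cell junctions, was higher by 1.00 ± 0.12 (SE; adjusted p = 0.000832 with edgeR), the imprinted gene Dlk1 by 2.50 ± 0.37, the retinoic acid receptor gene Rara by 0.66 ± 0.11, the transcription factor gene Hnf4a by 0.98 ± 0.19 and the galanin receptor gene Galr1 by 0.62 ± 0.12. Serpinb6a (−0.51 ± 0.08), Sgcz (−2.22 ± 0.34) and Maob (−0.68 ± 0.13) were lower, and Gcg had −8.63 ± 1.37 (adjusted p = 0.00870). Cholesterol synthesis genes had a median of 0.62 (adjusted p = 1.34e-12; adjusted p = 0.376 with an estimated correlation). In fasted mice, where the 2 libraries enter through the shared spread, 26 genes were called. Among them were Snrnp70 (0.81 ± 0.15), Srek1 (0.66 ± 0.13), Rbm39 (0.43 ± 0.08) and Tardbp (0.68 ± 0.14), all of RNA processing, and Dusp4 (−1.27 ± 0.24). The genes named from this fit were chosen after their values were seen. Whether RNA processing genes are frequent among the 26 was not tested.

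A hypothesis from the calls of Luc7l, Rbm5, Srsf7 and Ddx39b is that splicing factor genes may be higher as a group in β-cells of DT mice. A list drawn by gene symbol after these names were seen, without the genes called with all libraries, had 118 tested members and a camera p of 0.000634 with an estimated correlation for DT against control averaged over feeding. Without any gene called with or without mice 13 and 20 it had 108 members, a median of 0.12 against 0.01 for other genes, 86 members above 0, 0 called with edgeR, and a camera p of 0.00189 from limma. Of 100 splits of the mice 1, the real one, gave a p as small (smallest other 0.0104), but the list was drawn from calls in the real grouping, so neither these p values nor the splits decide, and chance cannot be excluded. The median was 0.14 in fasted mice, where 1 of 100 splits, the real one, gave a p as small (smallest other 0.00635), and 0.09 in refed mice, where 5 of 100 did; for the interaction 43 of 100 did.

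The result for the 108 genes depended on the processing. The p was 0.00276 with the library kind as covariate, 0.00480 without mice 13 and 20, 0.00658 with RLE scaling, 0.0509 in the other library kind alone and 0.260 without scaling beyond library size, where the estimated correlation was 0.262 and the median in refed mice −0.00431. Of the same genes 40 were higher and 16 lower after refeeding on average, so a difference in feeding state between the mice is an untested alternative.

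A further hypothesis is that less cAMP signalling without glucagon from α-cells may lower cAMP pathway genes in fasted DT mice. CREB target genes, expected to follow, had a median of −0.05 in fasted DT mice and an adjusted p of 0.206 with camera, which does not decide between less signalling and none.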
